A study of Mus musculus with 227 samples.

How the data were processed

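RNA was measured in 227 libraries of primary mouse cerebrocortical cultures, 218 from cultures treated with 1 drug each and 9 from cultures treated with vehicle (0.2% DMSO). Groups were taken from the agent named in the sample labels, and the run code from the sequencing information in the labels. The sources used here give no doses. The submitters' notes name STAR 2.4.0, Subread 1.4.6, limma and edgeR 3.10.5 for mm10, without saying which step each served. The deposited counts, made by the authors, are whole reads per Ensembl gene and are not normalized. The deposited RPKM values, made by the authors, equal the count times a constant divided by the deposited gene length and the column total, checked on 4169365 values (largest relative difference 0.00063), and were not used further. The count table held 31689 genes, and 31328 of their identifiers were found in the GENCODE vM21 annotation, all on the same chromosome. No reads were available, so alignment and counting were not repeated.

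Library totals were 22.02 M to 65.19 M counts (median 34.99 M; vehicles 31.4 M to 43.77 M), with 2.90 to 4.36% on mitochondrial genes. The non-coding gene Yam1 took 0.140 to 9.59% of counts. The principal component with most variance (33.6%) had an R squared of 0.481 with run code. No library was nearly identical to another among 25651 pairs, with a lowest chi-square per gene of 2.36 over genes with a mean count of 50 or more.

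Counts were analysed in R 4.3.3. The main test was edgeR 4.0.16 with TMM factors (0.938 to 1.06), its default filter on low counts and quasi-likelihood F tests, with a Benjamini-Hochberg adjusted p under 0.05 as threshold. Each drug library was compared with the 9 vehicles (15380 to 15520 genes tested), and each vehicle with the other 8. In 9 classes the member drugs were treated as replicates and compared with the 9 vehicles, and 9 pairs of analogs were compared with each other. Errors of log2 fold changes are standard errors, errors of CPM are SDs, and intervals are 95% intervals. A single library gives no error of its own, so the spread of the vehicles stands for it. Tested on simulated data, 1 library against 9 recovered 65.7% of genes changed by 1 log2 unit, 88.1% at 2 and 86.4% at 3. It called 11 unchanged genes of 13776 tested, and 5 libraries against 9 recovered 88.1%, 98.5% and 100%. The simulation drew each gene independently from the spread of the vehicles, without run-code effects or relations between genes. These rates therefore leave out such sources of spread in the real libraries.

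The 31 gene lists, the classes, the pairs, the tests and the rule for named genes were fixed before the data were examined. The lists were activity-regulated genes, AhR targets, astrocyte markers, ATF4 stress response, cholesterol biosynthesis, circadian clock, endothelial markers, ER chaperones, excitatory neuron markers, fibroblast markers, glucocorticoid response, heat shock, hypoxia response, inhibitory neuron markers, interferon response, LXR targets, lysosomal genes, microglia markers, mitochondrial transcripts, mural cell markers, neurogenetic disease genes, neuron markers, NF-kB inflammation, NRF2 targets, oligodendrocyte markers, oligodendrocyte precursor markers, p53 targets, PPAR targets, proliferation, retinoic acid response and thyroid hormone response. They hold 384 genes, of which 383 were found by symbol and 1 by an older symbol. List members were counted as passing in the test of all genes and again with p adjusted over the list alone. Lists were also tested per class with camera on voom values of limma 3.58.1 (preset correlation 0.01 and an estimated correlation) and with fry, as 279 tests. A list score is the mean log2 CPM (prior count 1) of list members with a mean CPM of 1 or more, minus the vehicle mean. Own-list scores of classes were compared by exact two-sided permutation, adjusted over 9 classes, and screen-wide scores were given beside the vehicle range without a test.

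The rule named, for each class, up to 10 largest rises and 10 largest falls past the threshold with a mean CPM of 1 or more and the same side of the vehicle mean in every member library, plus the class's own list. For the 6 drugs outside the 9 classes with the most genes, it named up to 5 rises and 5 falls past the threshold. The rule further named, per list, the 3 highest and 3 lowest drugs. It also named 6 disease genes by number of drugs, and for each pair the largest difference each way. Genes given for single drugs of the 9 classes, and list members past the threshold in a single drug, were not part of the rule fixed beforehand. The text gives a part of these names, and some genes that the rule named are not reported here. Ties were ordered alphabetically.

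Alternatives fixed beforehand were RLE factors, DESeq2 1.42.0 with Wald tests, no filter on low counts, limma over all 227 libraries with a term for run code, leaving out each member drug, scores centred on the run-code median and RLE-scaled scores. The run-code model compared a library or class with all other libraries, other drugs included, and not with the vehicles alone. Leaving out each vehicle, and contrasts between drugs beyond the 9 pairs, were added after the data were seen. Splits exchanged class and vehicle labels, with the real labels as 1 of 60 splits per class, for the 7 classes with 3 or more drugs. All libraries were kept.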

Results

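To identify brain-penetrant drugs that change the expression of genes relevant to neurogenetic disease, primary mouse cerebrocortical cultures were exposed to 218 drugs and profiled by RNA sequencing. Cultures were prepared at embryonic day 16.5, kept for 21 days in vitro and treated for 8 h. Each drug had 1 library and vehicle (0.2% DMSO) had 9, in 9 sequencing run codes, 3 of which held no vehicle. Among the drugs with a gene past the threshold, Ciprofibrate, Clofibrate, Diflunisal, Luteolin and Mitoxantrone·HCl came from these 3. Their comparisons with vehicle cannot tell drug from run code. Each of the other drugs with such a gene shared its run code with only 1 or 2 of the 9 vehicles. Run code was not a term in the edgeR comparisons, so part of their counts may also go with it. Libraries held 22.02 M to 65.19 M counted reads (median 34.99 M), and 17790 to 19360 genes had at least 1 read. Each drug was compared with the 9 vehicles, drugs of 9 classes were then pooled as replicates of their class, and 9 pairs of close analogs were compared directly. A lone library was assumed to vary like the vehicles, so no replicate check of a single drug was possible.

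Of the 218 drugs, 17 had at least 1 gene past the threshold (edgeR, adjusted p under 0.05). The largest responses were those to Nilotinib, a kinase inhibitor (1891 genes), and Fenofibrate, a lipid-lowering fibrate (1646 genes). Ciprofibrate (80 up and 32 down), Aminophylline (75), Mitoxantrone·HCl (62), Dexamethasone (49), Formoterol (40), Luteolin (38), Betamethasone (29), Liothyronine·Na (26), Levothyroxine·Na (23), Diflunisal (20) and Quercetin (9) followed. CE-326597 had 3 genes, Probenecid 2, and Isotretinoin and Clofibrate 1 each. No gene passed in edgeR when each vehicle was compared with the other 8, and a drug had a median of 288.5 genes at unadjusted p under 0.05 against 628 for a vehicle. DESeq2 gave 98 drugs with a call, 32 of them above the highest vehicle count (17), and limma over all libraries with a run-code term gave 28 above the highest vehicle (15). Of the 17 drugs, 15 were above the highest vehicle in DESeq2 and 14 in the run-code model. Drugs with no call in edgeR also had many elsewhere, namely Oxaprozin (996), Nortriptyline·HCl (780), Orlistat (346) and Leucovorin Calcium Pentahydrate (313) in DESeq2, and Ursodiol (2859, below only Fenofibrate and Nilotinib) and CP-448187 (571) in the run-code model.

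**Figure D1:**
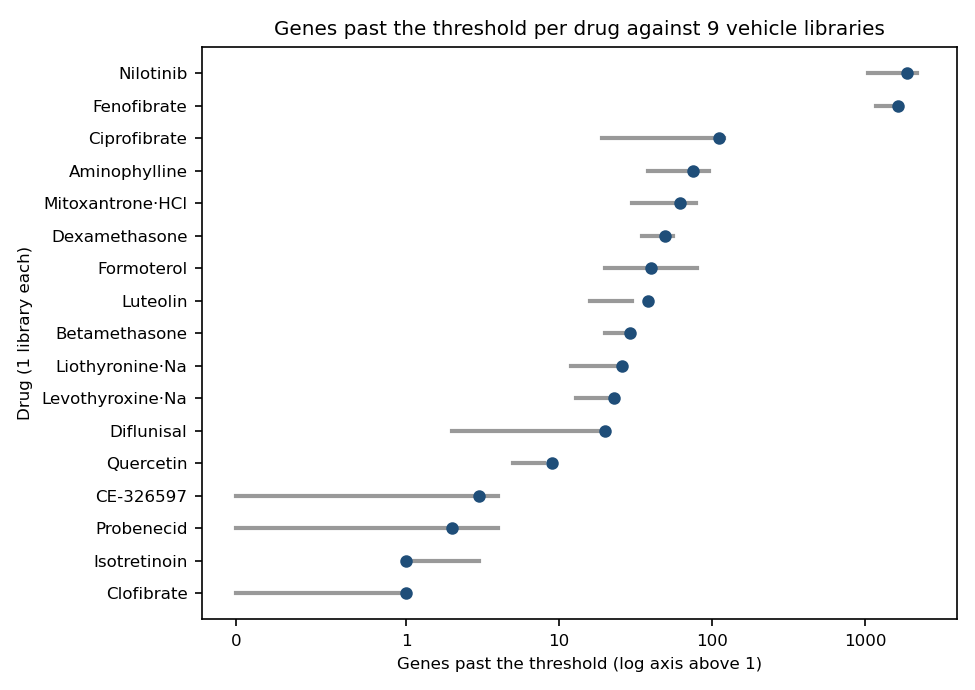
Genes past the threshold for the 17 drugs with at least 1 call (1 library each against 9 vehicles, edgeR). Nilotinib and Fenofibrate gave 1891 and 1646 genes.

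To ask whether glucocorticoids induced their known target genes, Dexamethasone, Betamethasone and Cortisone Acetate were compared with vehicle. As a class (n = 3), 2 genes rose. These were Plin4, which coats lipid droplets (log2 fold change 4.41 ± 0.583 SE; ENSMUSG00000002831.11, chromosome 17, 56100591 to 56109803, mm10), and Map3k6, a stress-activated kinase (4.06 ± 0.51; ENSMUSG00000028862.6, chromosome 4, 133240818 to 133252929), each with an edgeR adjusted p of 0.0364. Map3k6 averaged 7.51 ± 5.99 CPM in the class and 0.451 ± 0.159 CPM in the 9 vehicles (SD). They were the 2 of the 20 tested glucocorticoid response genes that passed, with 12 passing when adjusted over the list alone, and the list median was 0.671. Tsc22d3, which encodes the anti-inflammatory leucine zipper protein GILZ, was at 1.76 ± 0.263 (edgeR adjusted p = 0.0723), and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 1.734 ± 0.295 (0.101). Per1 and Sgk1, a circadian repressor and a kinase, were at 0.16 and -0.08 without passing (Sgk1 0.213 with a run-code term). By camera the list had an adjusted p of 1.04e-20 and an adjusted p of 0.799 with an estimated correlation. No gene passed without Dexamethasone, without Betamethasone or without any 1 of the 9 vehicles, and 78 passed without Cortisone Acetate. DESeq2 gave 45 genes and limma with a run-code term 1.7e+02. Of 60 splits of these libraries, the real one included, only the real one gave 2 genes. The highest other gave 1, and 2 other splits had a call. A count of 2 against 1, not adjusted over the classes split, cannot exclude chance.

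In the single libraries, Dexamethasone raised 48 genes and lowered 1, and Betamethasone raised 26 and lowered 3. Plin4 rose by 5.264 ± 0.433 and 4.54 ± 0.462 log2 units, Map3k6 by 4.71 ± 0.279 and 4.47 ± 0.284, and Fkbp5 by 2.29 ± 0.168 and 2.03 ± 0.172 (n = 1 each against 9). Tsc22d3 (ENSMUSG00000031431.11, chromosome X, 140539528 to 140600659) rose by 2.36 ± 0.0806 with Dexamethasone, with an edgeR adjusted p of 2.62e-07. Lcn2, which encodes an iron-sequestering secreted protein, rose by 3.422 and 3.58, and Sult1a1, a phenol sulfotransferase, by 1.94 and 1.70. Pdk4, which limits glucose oxidation, rose by 2.36 ± 0.293 and Hif3a, a hypoxia-inducible factor subunit, by 2.248 ± 0.256 with Dexamethasone. With Betamethasone, Mfsd2a, the lysolipid transporter of the blood-brain barrier, rose by 2.23. Rasa3, a GTPase-activating protein, fell with either drug, at -0.43 and -0.47. Of the 20 list genes, 8 rose with Dexamethasone (12 adjusted over the list alone, median 1.1) and 5 with Betamethasone (10 adjusted over the list alone, median 0.68). Both comparisons used the same 9 vehicles, and 22 genes rose in both (0.076 for independent lists). With separate vehicles 20 and 0 genes passed, so none could be shared, and that comparison does not test the overlap. DESeq2 and the run-code model gave 2.7 and 2.6 times as many genes for Dexamethasone, and 74 and 75 for Betamethasone.

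Dexamethasone and Betamethasone are epimers at the carbon that bears the ring methyl group. Their glucocorticoid response scores differed by 0.431 (95% interval -0.0975 to 0.96), and no gene differed between them in edgeR (809 at unadjusted p under 0.05, 1 gene in DESeq2). The sources used here give no doses for any drug, so matched doses cannot be assumed for this or any other pair. Of the 9 pairs only the thyroid hormones and Quercetin with Kaempferol shared a run code, so in the others drug and run code cannot be told apart.

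To ask whether thyroid hormones changed the cultures, Levothyroxine·Na and Liothyronine·Na (n = 2) were compared with vehicle. Of 15059 genes tested 1.3% passed, 51 as falls and the other 74% as rises. Hr, a corepressor of the thyroid hormone receptor (ENSMUSG00000022096.12, chromosome 14, 70552212 to 70573548), rose by 3.02 ± 0.211 log2 units, from 3.78 ± 0.946 to 30.5 ± 0.795 CPM, with an edgeR adjusted p of 4.96e-05. Stat5a, a signalling transcription factor (ENSMUSG00000004043.12, chromosome 11, 100859351 to 100885169), rose by 3.27 ± 0.298, and Dio3, the deiodinase that inactivates thyroid hormone, by 2.47 ± 0.414. Ighm, the immunoglobulin mu heavy chain, rose by 6.167 ± 0.697, Prlr, the prolactin receptor, by 2.82 ± 0.399, Lpo, lactoperoxidase, by 2.73 ± 0.31, and Ky, a muscle protein, by 2.56 ± 0.269. Bcar3, an adaptor protein, rose by 2.44 ± 0.298 and Gbp3, a guanylate-binding protein, by 2.43 ± 0.263. Among falls were Hes5, a Notch effector (-2.52 ± 0.444), A830029E22Rik (-2.19), Nnmt, nicotinamide N-methyltransferase (-1.74 ± 0.337), Npsr1, the neuropeptide S receptor (-1.41), Ankrd34c (-1.37) and Gcnt2 (-1.33).

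Of the 8 tested thyroid hormone response genes, Hr and Dio3 rose and 6 did not pass; adjusted over the list alone, 5 rose and 2 fell. Dbp, a circadian transcription factor, was at 0.78 ± 0.175, Klf9, a hormone-induced transcription factor, at -0.01 ± 0.263 (0.626 with a run-code term), Nrgn, a calmodulin-binding postsynaptic protein, at -0.81 ± 0.227, and Thrsp, a lipogenic protein, at -0.78 ± 0.214. Excitatory neuron markers had a median of -0.568 (4 of 6 fell adjusted over the list alone) and neuron markers of -0.366 (none of 8), and 1 of 5 oligodendrocyte precursor markers fell (1 adjusted over the list alone). The list median was 0.468, with a camera adjusted p of 0.0155, an adjusted p of 0.799 with an estimated correlation, and a fry adjusted p of 0.00562. Both libraries shared a run code, whose lone vehicle was vehicle library 4. Hypoxia response genes had a median of -1.44 (1 of 14 fell, Ankrd37; 13 fell adjusted over the list alone), with a camera adjusted p of 1.41e-05 and an adjusted p of 0.799 with an estimated correlation. Once centred on their run code, the hypoxia scores were -0.087 and -0.0658, within the vehicles (-1.13 to 1.37). Activity-regulated genes likewise had a median of -1.60 (1 of 25 fell) and centred scores of -0.12 and -0.18. Left-out libraries moved the count to 26 without Levothyroxine·Na, 23 without Liothyronine·Na, 306 without vehicle library 2, and 0.56 and 0.61 times the full count without 5 and without 9. DESeq2 gave 960 genes and limma with a run-code term 372, which kept 70% of the original calls but not those of A830029E22Rik, Npsr1, Ankrd34c and Ankrd37.

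The single hormones raised Hr by 3.04 ± 0.277 (Levothyroxine·Na) and 2.99 ± 0.279 (Liothyronine·Na), and Stat5a by 3.37 ± 0.391 and 3.152 ± 0.406, each with n = 1 against 9. With the same 9 vehicles 16 genes rose in both (0.036 for independent lists). With separate vehicles 1 and 0 genes passed, so none could be shared, and the overlap was not tested. Levothyroxine carries an additional iodine on its outer ring. Its thyroid hormone response score minus that of Liothyronine·Na was -0.02 (95% interval -0.576 to 0.536), with no gene past the threshold in edgeR or DESeq2 and 0.66% at unadjusted p under 0.05. Left-out vehicles moved the count of 23 for Levothyroxine·Na to 13 without library 5, and DESeq2 gave 94 genes and the run-code model 5.2 times as many as edgeR. For Liothyronine·Na the count of 26 moved to 12 without library 4 or 5, 15 without 6 and 16 without 7, and DESeq2 and the run-code model gave 5.8 and 4.5 times as many.

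To ask whether benzodiazepines, which enhance inhibition through GABA-A receptors, changed activity-dependent transcription, Clonazepam, Lorazepam, Oxazepam, Temazepam and Triazolam (n = 5, 4 run codes) were compared with vehicle. Of 25 activity-regulated genes, 18 fell, with a median log2 fold change of -1.80. Ptgs2, the inducible cyclooxygenase (ENSMUSG00000032487.8, chromosome 1, 150100031 to 150108227), fell from 28.6 ± 27.7 to 1.30 ± 0.597 CPM (-4.48 ± 0.992; edgeR adjusted p = 0.0251). Npas4, a neuronal activity-dependent transcription factor (ENSMUSG00000045903.8, chromosome 19, 4984355 to 4990316), fell from 56.9 ± 54 to 4.46 ± 1.56 CPM (-3.67 ± 0.801). Bdnf, a neurotrophin (-3.17 ± 0.663; ENSMUSG00000048482.12, chromosome 2, 109674700 to 109727007), Nptx2, a synaptic pentraxin (-2.99 ± 0.648), and Fosb, an AP-1 subunit (-3.22 ± 0.808), fell with them. So did Inhba, an activin subunit (-3.28 ± 0.822), Arc, a regulator of synaptic receptors (-2.46 ± 0.48; ENSMUSG00000022602.12, chromosome 15, 74669083 to 74672570), and Egr1, a zinc-finger immediate early gene (-1.68 ± 0.332). Fos, the prototype immediate early gene (ENSMUSG00000021250.11, chromosome 12, 85473890 to 85477273), fell by 2.116 ± 0.544. Egr2 (-2.14 ± 0.584), Junb (-1.35) and Btg2 (-0.01) did not pass.

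Across all genes 287 rose and 282 fell with the benzodiazepines. Other large falls were Krt6a, a keratin (-5.43 ± 1.36), Fam150b, a ligand of ALK receptors (-3.87 ± 0.62), and Pthlh, a parathyroid hormone-related peptide (-2.57 ± 0.499). Rises were smaller and included Adamts2, a procollagen protease (1.37 ± 0.168), Chrna10, a nicotinic receptor subunit (1.33 ± 0.216), and Dmrt2, a transcription factor (1.31 ± 0.273). Slc44a5, a choline transporter-like protein (ENSMUSG00000028360.9, chromosome 3, 153973436 to 154271722), rose by 1.255 ± 0.15 with the lowest edgeR adjusted p of the named rises, 0.000934. Scube2 (1.04 ± 0.194) and Hrk, an apoptosis activator (0.83 ± 0.131), also rose. The activity-regulated list had 24 of 25 falls adjusted over the list alone, a camera adjusted p of 5.78e-14 and an adjusted p of 0.799 with an estimated correlation.

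The count of 569 depended on the libraries used. It moved to 225 without Clonazepam and to 0.3, 0.28 and 0.3 times the full count without Lorazepam, Temazepam and Triazolam, and among vehicles to 298 without library 5, 302 without 6, 322 without 7 and 325 without 8. DESeq2 gave 1291 genes, limma with a run-code term 1882, of which 541 were among the 569, and testing without a filter on low counts 345, without Fos, Fosb, Inhba and Krt6a. Of 60 splits of these libraries, the real one included, 3 gave as many genes, so chance cannot be excluded. The highest other split, Lorazepam with vehicle libraries 5, 6, 7 and 8, gave 6218 genes, which points to a structure of the samples.

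**Figure D2:**
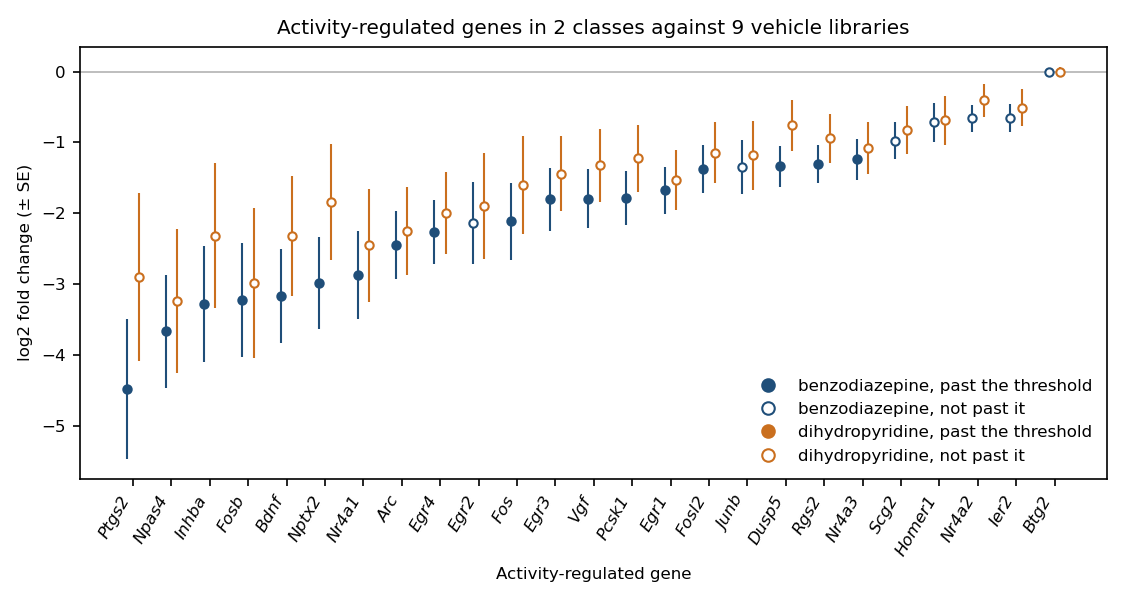
Log2 fold changes of the 25 activity-regulated genes with benzodiazepines (n = 5) and dihydropyridines (n = 3) against 9 vehicles. Of these, 18 fell with benzodiazepines and 0 passed with dihydropyridines.

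Dihydropyridine calcium channel blockers (Nifedipine, Nimodipine and Felodipine, n = 3) gave low values of the same list, with no gene past the threshold in edgeR or in limma with a run-code term, 29 in DESeq2 and 861 at unadjusted p under 0.05. Npas4 was at -3.24 ± 1.02 (edgeR adjusted p = 0.838), Arc at -2.25 ± 0.62 (0.708) and Egr1 at -1.53 ± 0.42 (0.696). The list median was -1.44, and 17 of 25 genes passed, all as falls, when adjusted over the list alone. By camera the list had an adjusted p of 3.61e-13 and an adjusted p of 0.799 with an estimated correlation. Another split of these libraries gave 1629 genes, which points to a structure of the samples.

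The mean own-list score, the log2 CPM of a list relative to vehicle, was compared exactly for each class. Activity-regulated genes scored -1.68 with benzodiazepines (5 drugs, -1.91 to -1.43; 9 vehicles, -1.21 to 1.2), with an exact permutation p of 0.0035 and a Benjamini-Hochberg adjusted p of 0.0315 over the 9 classes. The same list scored -1.27 with dihydropyridines (-1.57 to -0.989), with an exact p of 0.05 and an adjusted permutation p of 0.112. Glucocorticoid response genes scored 0.684 (0.027 to 1.23; vehicles, -0.24 to 0.212; exact p = 0.0227, adjusted permutation p = 0.0682). The thyroid hormone response scored 0.471 (0.785 centred on run code), with the smallest exact p that 2 libraries against 9 can give, 0.0182 (adjusted permutation p = 0.0682). Remaining scores were -0.363 for cholesterol biosynthesis with tricyclic antidepressants (-0.163 centred on run code; exact p = 0.171), -0.212 for cholesterol biosynthesis with SSRIs (exact p = 0.32), 0.0321 for cholesterol biosynthesis with statins (-0.0233 centred on run code; exact p = 0.945), -0.271 for AhR targets with flavonoids (exact p = 0.122) and 0.166 for PPAR targets with fibrates (exact p = 0.316).

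**Figure D3:**
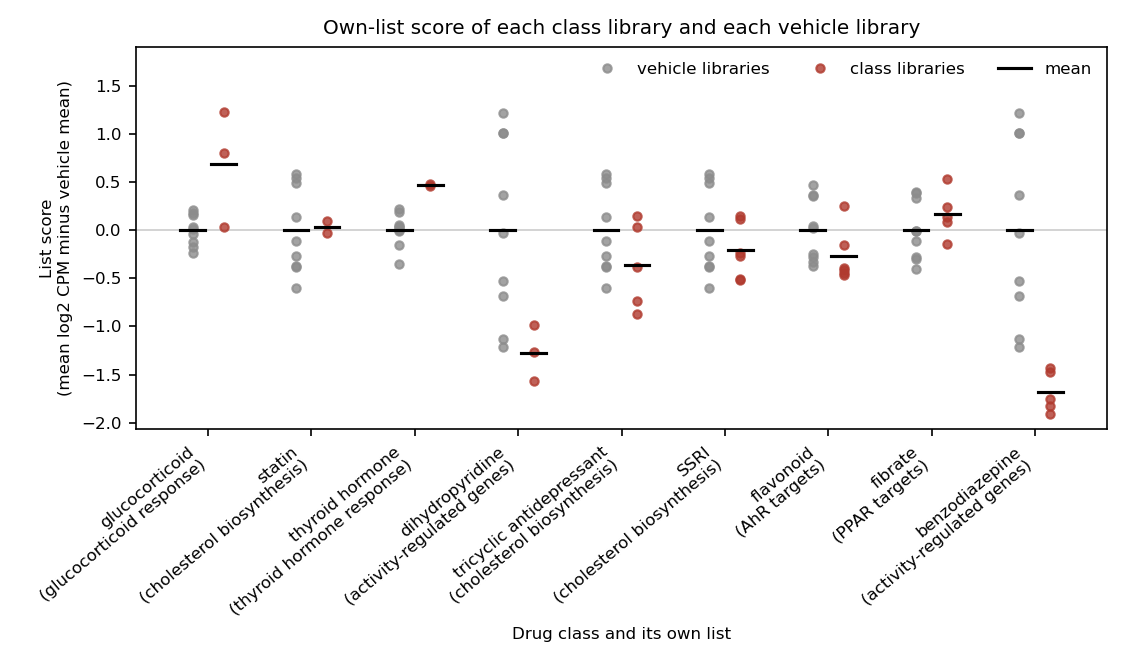
Own-list score of each class library and each vehicle library (9 vehicles). The benzodiazepine mean was -1.68.

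To ask whether fibrates, which activate PPAR alpha, shared a response, Fenofibrate, Gemfibrozil, Bezafibrate, Clofibrate and Ciprofibrate (n = 5) were pooled. The PPAR target gene Angptl4, an inhibitor of lipoprotein lipase (1.616 ± 0.494; edgeR adjusted p = 0.311), did not pass. No gene passed in edgeR, with 1793 at unadjusted p under 0.05, 74 genes in DESeq2 and 2045 in limma with a run-code term. The ER chaperones had a median of 0.283 (9 of 14 rose when adjusted over the list alone), with a camera adjusted p of 7.97e-06 and an adjusted p of 0.799 with an estimated correlation. Another split of these libraries gave 1240 genes, which points to a structure of the samples.

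Fenofibrate alone raised 904 genes and lowered 742. Mx2, an interferon-induced GTPase (ENSMUSG00000023341.12, chromosome 16, 97535308 to 97560900), rose by 4.36 ± 0.194 with an edgeR adjusted p of 8.48e-07. Myod1, the myogenic factor, rose by 5.82 ± 0.597 and Tmem140, a membrane protein, by 4.936 ± 0.412. Il11, a cytokine, rose by 4.372 ± 0.369 and Lincpint, a p53-induced non-coding RNA, by 4.371 ± 0.428. List counts for this drug were not tested against the share of all genes that passed, given below with the disease genes. Small ones, such as that of the PPAR targets, do not stand out from it. Stress genes Ddit3, which encodes CHOP (2.95 ± 0.187; ENSMUSG00000025408.13, chromosome 10, 127290774 to 127296288), Atf3 (3.822 ± 0.528) and Hspa5, the ER chaperone BiP (1.173 ± 0.0772; ENSMUSG00000026864.11, chromosome 2, 34771970 to 34777547), rose. Of 17 ATF4 stress response genes 6 rose (9 up and 1 down adjusted over the list alone), of 14 ER chaperones 5 (9 adjusted over the list alone) and of 18 lysosomal genes 6 (8 adjusted over the list alone), with Gla, alpha-galactosidase, at 1.80 ± 0.107, Neu1, a sialidase, at 0.78 ± 0.0893 and Ctsb, a cathepsin, at 0.66 ± 0.173. Of 10 circadian clock genes 3 rose (3 adjusted over the list alone), among them Nr1d1, which encodes REV-ERB alpha (1.41 ± 0.139), and Ciart (2.273 ± 0.448). Of 13 p53 targets 3 rose and 1 fell. Cd36, a fatty acid translocase, was the 1 of 11 PPAR targets that rose (1 adjusted over the list alone).

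Of 5 mitochondrial transcripts 3 fell with Fenofibrate (4 adjusted over the list alone), namely mt-Nd2 (-0.68 ± 0.161), mt-Cytb (-0.67 ± 0.17) and mt-Nd4 (-0.51 ± 0.139). Gad2, a GABA-synthesizing enzyme (-1.39 ± 0.249), and Slc32a1, the vesicular GABA transporter (-0.72 ± 0.174), were the 2 of 8 inhibitory neuron markers that fell (5 adjusted over the list alone). The largest falls were mt-Tt, a mitochondrial transfer RNA (-4.39 ± 1.02), Ovol2, a zinc-finger repressor (-3.19 ± 0.469), Hes5, a Notch effector (-2.90 ± 0.624), Lfng, a Notch modulator (-2.82 ± 0.521), and Gm3294 (-2.24). DESeq2 gave 2496 genes and limma with a run-code term 4209.

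Ciprofibrate raised 80 genes and lowered 32. Of 14 ER chaperones 7 rose (12 adjusted over the list alone, median 0.549), with Hspa5 at 1.157 ± 0.0773 and Sdf2l1, an ER chaperone cofactor, at 1.38 ± 0.117. Il11, a cytokine, rose by 3.35 ± 0.414, Tgm1, a transglutaminase, by 3.639 ± 0.565, Tm4sf1, a membrane protein, by 3.05 ± 0.579 and Zfp36, which destabilizes cytokine mRNA, by 3.0 ± 0.49. Inpp5d, a lipid phosphatase (-2.51 ± 0.233; edgeR adjusted p = 0.00123; ENSMUSG00000026288.12, chromosome 1, 87620312 to 87720507), Ovol2 (-3.38 ± 0.48), Baiap2l2 (-1.84 ± 0.287), Has3 (-1.66 ± 0.227) and Adamts15 (-1.60 ± 0.177) fell. Fenofibrate and Ciprofibrate shared 44 rising and 27 falling genes with the same 9 vehicles (4.4 and 1.5 for independent lists). With separate vehicles 630 and 1 genes passed, so at most 1 could be shared, and that 1, a rise, was. The count moved to 59 without vehicle library 4, 19 without 5, 56 without 6, 63 without 7, 58 without 8 and 49 without 9, and DESeq2 gave 564 genes, the run-code model 544 and testing without a filter 71. Clofibrate raised Crem, a cAMP-responsive modulator of transcription (1.06 ± 0.116; edgeR adjusted p = 0.0377). That call was absent without any of vehicle libraries 1 to 5 or 7 to 9, and DESeq2 gave 31 genes and the run-code model 3.

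Flavonoids (Genistein, Kaempferol, Quercetin, Luteolin, Apigenin and Daidzein, n = 6) gave no gene in edgeR, with 1166 at unadjusted p under 0.05, 1 gene in DESeq2 and 374 in limma with a run-code term. AhR targets Aldh3a1, an aldehyde dehydrogenase, and Cyp1b1, a cytochrome P450, were at 0.89 ± 0.267 and -0.88 ± 0.356, with an edgeR adjusted p of 0.594 each. Quercetin raised 9 genes, 5 of them among 12 NRF2 targets (9 adjusted over the list alone, median 1.35). Srxn1, a sulfiredoxin (2.09 ± 0.177; ENSMUSG00000032802.8, chromosome 2, 152105516 to 152111376), Gclm, of glutathione synthesis (1.74 ± 0.15), Hmox1, heme oxygenase 1 (2.64 ± 0.365), Osgin1, an oxidative stress response protein (2.04 ± 0.217), and Gsr, glutathione reductase (1.37 ± 0.123), rose. The count of 9 moved to 5 without vehicle library 1, 6, 7 or 9, and DESeq2 gave 32 genes and the run-code model 44.

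Luteolin raised 34 genes and lowered 4. Il11, a cytokine, rose by 5.152 ± 0.35, Hmox1 by 2.62 ± 0.366 and Srxn1 by 1.516 ± 0.186, and Hspa5, the ER chaperone BiP, by 1.3 ± 0.0761 with an edgeR adjusted p of 5.12e-05. Of 14 ER chaperones 8 rose (12 adjusted over the list alone, median 0.791) and of 12 NRF2 targets 2 did (5 adjusted over the list alone). Btbd17 (-1.38), Rasa3, a GTPase-activating protein (-0.68 ± 0.0697), and Hnrnpdl (-0.61) fell. The count of 38 moved to 23 without vehicle library 1, 21 without 2, 16 without 5, 25 without 6, 20 without 7 and 21 without 9, and DESeq2 gave 344 genes, the run-code model 1384 and testing without a filter 25.

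Luteolin and Apigenin differ by a hydroxyl group on the B ring, and 3 genes separated them, each an ER chaperone gene higher with Luteolin and each with an edgeR adjusted p of 0.0177. These were Hspa5 (1.1 ± 0.117), Sdf2l1 (1.65 ± 0.181) and Creld2 (1.35 ± 0.154), with 300 genes at unadjusted p under 0.05 and 21 in DESeq2. Sdf2l1 was named by the rule fixed beforehand, and Hspa5 and Creld2 were chosen after their values were seen. Their AhR target scores differed by -0.0148 (95% interval -1.08 to 1.05). Quercetin and Kaempferol, which differ in the same way, had no gene past the threshold in edgeR (277 at unadjusted p under 0.05, 16 in DESeq2) and a score difference of 0.399 (-0.669 to 1.47). Genistein, which has an additional hydroxyl group, and Daidzein had none in edgeR or DESeq2 (91 at unadjusted p under 0.05) and a difference of 0.0202 (-1.05 to 1.09).

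Tricyclic antidepressants (Imipramine, Doxepin, Nortriptyline, Protriptyline and Trimipramine, n = 5) gave no gene in edgeR, with 3866 at unadjusted p under 0.05, 510 in DESeq2 and 3 in limma with a run-code term. Ebp, a sterol isomerase of cholesterol synthesis, was at -0.27 ± 0.0961. Neuron markers had a median of -0.348 (8 of 8 fell adjusted over the list alone), NRF2 targets 0.31 (9 of 12 rose adjusted over the list alone) and ATF4 stress response genes 0.388 (8 of 17 rose adjusted over the list alone). Their camera adjusted p were 0.000526, 0.000417 and 3.56e-05, each with an adjusted p of 0.799 with an estimated correlation. Left-out libraries gave 2 genes without Protriptyline, 1 without vehicle library 1 and 3 without library 3.

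The SSRIs (Escitalopram, Citalopram, Paroxetine, Fluoxetine, Fluvoxamine and Sertraline, n = 6) gave no gene in edgeR, DESeq2 or limma with a run-code term, and 1.2% of 14663 at unadjusted p under 0.05. The cholesterol biosynthesis list had a camera adjusted p of 1.41e-05 and an adjusted p of 0.799 with an estimated correlation. Another split of these libraries gave 3423 genes, which points to a structure of the samples. Citalopram·HBr, the racemate, and Escitalopram, its S-enantiomer, had a cholesterol biosynthesis score difference of -0.238 (95% interval -1.70 to 1.23), no gene past the threshold in edgeR, 0.75% of genes at unadjusted p under 0.05 and 1 gene in DESeq2. Statins (Lovastatin and Simvastatin, n = 2) left Sqle and Hmgcs1, which encode enzymes of cholesterol synthesis, at -0.06 ± 0.346 and -0.12 ± 0.459 (0.193 and 0.24 with a run-code term). No gene passed in edgeR, DESeq2 or limma with a run-code term, and 77 were at unadjusted p under 0.05. Simvastatin carries an additional methyl group on its ester side chain. The score of Lovastatin minus that of Simvastatin was 0.125 (-1.34 to 1.59), with no gene in edgeR or DESeq2 and 210 at unadjusted p under 0.05.

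Temazepam and Oxazepam differ by a methyl group on the ring nitrogen, and no gene separated them in edgeR (1893 at unadjusted p under 0.05, 18 in DESeq2). Their activity-regulated scores differed by 0.325 (95% interval -2.76 to 3.41). Aminophylline is the ethylenediamine combination of Theophylline, and 2 genes separated them, Sltm, a nuclear RNA-binding protein (0.93 ± 0.105), and Insr, the insulin receptor (0.85 ± 0.0988), higher with Aminophylline and each with an edgeR adjusted p of 0.0304. Insr was chosen after its values were seen. There were 1038 genes at unadjusted p under 0.05 and 1.1e+02 in DESeq2, and none passed without a filter on low counts. Their activity-regulated scores differed by -1.38 (-4.47 to 1.70).

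Among drugs outside these classes, Nilotinib raised 959 genes and lowered 932. Ccl2, a monocyte chemoattractant (ENSMUSG00000035385.5, chromosome 11, 82035571 to 82037453), rose by 6.69 ± 0.449 log2 units, from 0.37 to 38.1 CPM, with an edgeR adjusted p of 3.61e-05. Cxcl1, a neutrophil chemoattractant (5.39 ± 0.372; ENSMUSG00000029380.11, chromosome 5, 90891241 to 90893115), Cxcl2 (5.01 ± 0.682), Cxcl10, an interferon-induced chemokine (4.98 ± 0.545), and Gbp5, a guanylate-binding protein (5.176 ± 0.597), rose as well. Of 11 NF-kB inflammation genes 6 rose (7 adjusted over the list alone, median 2.84), among them Il6, a cytokine (4.74 ± 0.613), Lcn2 (3.98 ± 0.545) and Icam1, an adhesion molecule (2.84 ± 0.654). Of 17 ATF4 stress response genes 7 rose (10 adjusted over the list alone), among them Chac1, a glutathione-degrading enzyme (2.34 ± 0.25), Trib3, a pseudokinase (2.408 ± 0.411), and Ddit3 (1.76 ± 0.208). Of 14 ER chaperones 6 rose (7 adjusted over the list alone), with Hspa5 at 0.64 ± 0.081. Of 10 heat shock genes 3 rose, among them Hspa1a, an inducible HSP70 (1.38 ± 0.194); adjusted over the list alone 4 rose and 1 fell, and the list median of -0.0205 and mean of 0.27 differ in sign from each other.

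List counts for Nilotinib were likewise not tested against the share of all genes that passed, given below with the disease genes. A small one, such as that of the excitatory neuron markers, need not stand out from it. Genes of dividing cells and of oligodendrocyte precursors fell with Nilotinib. Of 12 proliferation genes 7 fell (10 adjusted over the list alone, median -0.865), including Mki67, a marker of cycling cells (-0.91 ± 0.221), Cdk1, the mitotic kinase (-1.21 ± 0.273), and Top2a, a topoisomerase (-0.92 ± 0.201). Of 5 oligodendrocyte precursor markers 3 fell (4 adjusted over the list alone, median -1.77), namely Cspg4, the NG2 proteoglycan (-2.36 ± 0.503), Pdgfra, the PDGF receptor alpha (-1.82 ± 0.309), and Olig2, a lineage factor (-0.92 ± 0.167). Of 8 neuron markers 3 fell (6 adjusted over the list alone, median -0.662), Snap25, of synaptic vesicle fusion (-0.80 ± 0.233), Syt1, a vesicle calcium sensor (-0.60 ± 0.149), and Tubb3, a neuronal tubulin (-0.73 ± 0.195). Camk2a, a synaptic kinase (-1.19 ± 0.328), was the 1 of 6 excitatory neuron markers that fell (4 adjusted over the list alone). The largest falls were Adora2a, an adenosine receptor (-3.85 ± 0.515; ENSMUSG00000020178.5, chromosome 10, 75316877 to 75334784), Hes5, a Notch effector (-2.87 ± 0.619), and Cdk18, a kinase (-2.197 ± 0.549). The count of 1891 moved to 1046 without vehicle library 5 and to 0.62 times as many without 9, and DESeq2 gave 3265 genes and the run-code model 3202.

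Aminophylline, a bronchodilator, raised 72 genes and lowered 3. Of 17 ATF4 stress response genes 4 rose (12 adjusted over the list alone, median 1.09): Trib3, a pseudokinase (3.05 ± 0.39; edgeR adjusted p = 0.0108; ENSMUSG00000032715.9, chromosome 2, 152337422 to 152344032), Chac1, a glutathione-degrading enzyme (1.88 ± 0.26), Ddit3, which encodes CHOP (1.59 ± 0.212), and Cth, of cysteine synthesis (1.513 ± 0.235). Gdf15, a stress-induced cytokine (2.62 ± 0.418), Ptx3, a long pentraxin (2.62 ± 0.399), Mei4, a meiotic recombination protein (2.353 ± 0.33), and Mmp28, a metalloproteinase (2.186 ± 0.377), rose too. Leng8 (-0.42 ± 0.0756) fell, with Khdrbs1 and Srsf7, which encode RNA-processing proteins (-0.39 ± 0.071 and -0.37 ± 0.0663). The count of 75 moved to 41 without vehicle library 4 and 38 without 5, and DESeq2 gave 294 genes and the run-code model 573.

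Mitoxantrone·HCl, a topoisomerase II inhibitor, raised 26 genes and lowered 36. Of 13 p53 targets 3 rose (10 adjusted over the list alone, median 1.02): Pmaip1, which encodes the apoptosis activator NOXA (1.71 ± 0.168; edgeR adjusted p = 0.00363; ENSMUSG00000024521.7, chromosome 18, 66458533 to 66465565), Aen, a nuclease (1.137 ± 0.141), and Mdm2, the p53 ubiquitin ligase (0.59 ± 0.09). Of 12 proliferation genes 4 fell (10 adjusted over the list alone, median -1.2), including Mki67, a marker of cycling cells (-1.82 ± 0.242; ENSMUSG00000031004.7, chromosome 7, 135689784 to 135716361), and Top2a, a topoisomerase (-1.55 ± 0.216). Other falls were Casc5, a kinetochore protein (-2.30 ± 0.253), Kif20a, a mitotic kinesin (-2.14 ± 0.313), Ube2c, a mitotic ubiquitin-conjugating enzyme (-1.87 ± 0.286), and Cenpf, of the kinetochore (-1.79 ± 0.277). Cxcl1, a chemokine (2.999 ± 0.469), Trim47 (1.79 ± 0.307), Dennd2c (1.57 ± 0.261) and Gtse1, a regulator of p53 (1.55 ± 0.141), rose. The count of 62 moved to 32 without vehicle library 4, 30 without 5, 40 without 6, 39 without 7 and 33 without 9, and DESeq2 gave 364 genes and the run-code model 234.

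Formoterol, an agonist of the beta-2 adrenergic receptor, raised 38 genes and lowered 2. Cnn1, a smooth muscle actin-binding protein (ENSMUSG00000001349.4, chromosome 9, 22099216 to 22109630), rose by 4.247 ± 0.354 with an edgeR adjusted p of 0.000956. Abhd15, a lipid-handling protein (2.62 ± 0.276), Mcam, an adhesion molecule (2.55 ± 0.342), Sod3, the extracellular superoxide dismutase (2.4 ± 0.403), and Tacr1, the substance P receptor (1.99 ± 0.217), rose with it. Srxn1, a sulfiredoxin, was the 1 of 12 NRF2 targets that rose (1.219 ± 0.19; 6 adjusted over the list alone). Etv4, a growth factor-responsive transcription factor (-1.48 ± 0.233), and Rasa3, a GTPase-activating protein (-0.53 ± 0.0685), fell. Of 6 excitatory neuron markers 5 passed, as falls, when adjusted over the list alone, with a median of -1.14. Luteolin and Formoterol shared 9 rising genes with the same 9 vehicles (0.077 for independent lists). With separate vehicles 6 and 0 genes passed, so none could be shared, and the overlap was not tested. The count of 40 moved to 80 without vehicle library 3, 23 without 4, 20 without 5, 22 without 6 and 25 without 9, and DESeq2 gave 851 genes and the run-code model 1.5e+02.

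Diflunisal, a salicylate anti-inflammatory drug, raised 13 genes and lowered 7. Adamts2, a procollagen protease (1.87 ± 0.293), Amz1, a metallopeptidase (1.254 ± 0.192), Hrk, an apoptosis activator (1.159 ± 0.163), and Camkk1, a calmodulin-dependent kinase (0.96 ± 0.146), rose. Inpp5d, a lipid phosphatase (-2.16 ± 0.226; edgeR adjusted p = 0.0116), Adamts15, a proteoglycan-cleaving protease (-1.52 ± 0.176), Fam43a (-0.91 ± 0.138), Dusp10, a MAP kinase phosphatase (-0.77 ± 0.117), and Afap1 (-0.60 ± 0.0927) fell. None of 10 circadian clock genes passed, and 6 passed, as rises, when adjusted over the list alone (median 0.502). The count of 20 moved to 9 without vehicle library 1 or 3, 7 without 2, 6 or 8, 8 without 4 or 9 and 2 without 5, and DESeq2 gave 334 genes, the run-code model 43 and testing without a filter 8. Of the genes named here only Inpp5d and Adamts15 also passed in the run-code model.

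CE-326597 raised Crem, a cAMP-responsive modulator of transcription (1.06 ± 0.117; edgeR adjusted p = 0.0381; ENSMUSG00000063889.14, chromosome 18, 3266048 to 3337748), Tpbg, a membrane glycoprotein (0.98 ± 0.123), and Mest, an imprinted hydrolase (0.72 ± 0.087). Activity-regulated genes had a median of 1.38 with this compound, and 3 of 25 passed, as rises, when adjusted over the list alone. Isotretinoin, a retinoid, raised Mbd1, a methyl-CpG-binding protein (0.88 ± 0.0787; edgeR adjusted p = 0.00502; ENSMUSG00000024561.8, chromosome 18, 74267605 to 74282732). With Isotretinoin all 10 interferon response genes and 3 of 8 retinoic acid response genes passed as rises when adjusted over the list alone (medians 1.58 and 0.758). Probenecid, a uricosuric drug, raised a pair of pseudogene or predicted transcripts, Rpl14-ps1 (3.01 ± 0.35) and Gm7964 (1.79 ± 0.206). The genes of Isotretinoin and Probenecid were chosen after their values were seen. The count for CE-326597 moved to 0 without vehicle library 1, 2, 5, 7 or 9 and 1 without 3 or 6, that for Probenecid to 4 without 1 or 5 and 0 without 3, 4, 6, 7, 8 or 9, and that for Isotretinoin to 3 without 1. DESeq2 gave 87 genes for CE-326597, 14 for Probenecid and 13 for Isotretinoin, both below the highest vehicle (17), and the run-code model 600 for CE-326597 and 5 for Isotretinoin.

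To describe the whole screen, each of 31 fixed gene lists was scored in every library relative to the vehicles, without a test. For signalling lists, ATF4 stress response genes were highest with Aminophylline and Nilotinib (1.2 each) and Fenofibrate (0.873) and lowest with Temazepam (-0.618; vehicles, -0.356 to 0.557). Glucocorticoid response genes were highest with Dexamethasone (1.23), Betamethasone (0.796) and Medroxyprogesterone Acetate, a progestin (0.478), and lowest with Trazodone·HCl (-0.331; vehicles, -0.24 to 0.212). Thyroid hormone response genes were highest with Liothyronine·Na (0.481) and Levothyroxine·Na (0.461) and lowest with Formoterol (-0.724; vehicles, -0.349 to 0.217). Retinoic acid response genes were highest with Isotretinoin (0.942) and lowest with Nimodipine (-0.789; vehicles, -0.466 to 0.449). NRF2 targets were highest with Quercetin (1.31) and Formoterol (0.76) and lowest with Voriconazole (-0.403; vehicles, -0.277 to 0.434). The p53 targets were highest with Mitoxantrone·HCl (0.93) and lowest with Methsuximide (-0.38; vehicles, -0.199 to 0.251). Activity-regulated genes were highest with CE-326597 (1.72) and Theophylline (1.6) and lowest with Clonazepam (-1.91) and Triazolam (-1.83; vehicles, -1.21 to 1.2).

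ER chaperones were highest with Luteolin (0.839), Ciprofibrate (0.654) and Fenofibrate (0.477) and lowest with Clonazepam (-0.155; vehicles, -0.0772 to 0.0483). Heat shock genes were highest with Nilotinib (0.293) and lowest with Cyproheptadine·HCl Sesquihydrate (-0.177; vehicles, -0.095 to 0.101). NF-kB inflammation genes were highest with Nilotinib (2.18) and Oxaprozin (1.5) and lowest with Luteolin (-1.55; vehicles, -0.616 to 1.30). Interferon response genes were highest with Oxaprozin (1.56) and Isotretinoin (1.48) and lowest with Betamethasone (-0.931; vehicles, -0.664 to 0.532). Hypoxia response genes were highest with Medroxyprogesterone Acetate (1.01) and lowest with Acetylcysteine (-1.45; vehicles, -1.26 to 0.728), but once centred on run code these were 0.373 and -0.177, within the vehicles (-1.13 to 1.37). Proliferation genes were lowest with Mitoxantrone·HCl (-1.2), Nilotinib (-0.716) and Hydroxyurea, an inhibitor of ribonucleotide reductase (-0.617), and highest with Vigabatrin (0.494; vehicles, -0.242 to 0.118).

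Cholesterol biosynthesis genes were highest with CE-326597 (0.816) and Luteolin (0.782) and lowest with Leucovorin Calcium Pentahydrate (-0.959; vehicles, -0.6 to 0.581). LXR targets were highest with Irbesartan (0.677) and lowest with Voriconazole (-0.516; vehicles, -0.41 to 0.362). PPAR targets were highest with Nortriptyline·HCl (0.758) and lowest with Luteolin (-0.528; vehicles, -0.406 to 0.398). AhR targets (3 genes scored) were highest with Probenecid (0.858) and lowest with Omeprazole (-0.968; vehicles, -0.369 to 0.464). Circadian clock genes were highest with Fenofibrate (0.574) and Diflunisal (0.416) and lowest with Formoterol (-0.382; vehicles, -0.193 to 0.073). Lysosomal genes were highest with Fenofibrate (0.444) and lowest with Methsuximide (-0.194; vehicles, -0.111 to 0.167). Mitochondrial transcripts were highest with Probenecid (0.395) and lowest with Fenofibrate (-0.56) and Ciprofibrate (-0.337; vehicles, -0.161 to 0.129).

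Oligodendrocyte precursor markers were lowest with Nilotinib (-1.45), Quinidine·HCl·H2O (-1.44) and Nebivolol·HCl (-1.30) and highest with Letrozole (0.439; vehicles, -0.643 to 0.321). Oligodendrocyte markers were lowest with Benztropine Mesylate (-1.73) and highest with Sulfamethoxazole (0.926; vehicles, -0.898 to 0.838). Scores of microglia and endothelial markers rest on 2 genes each, of mural cell markers on 3 and of fibroblast markers on 5. Microglia markers were lowest with Duloxetine·HCl (-1.80; vehicles, -0.822 to 0.865), fibroblast markers with Ramipril (-1.53; -0.878 to 0.914), mural cell markers with PF-04995274-00 (-1.61; -1.2 to 1.2) and endothelial markers with Rifampin (-1.49; -0.545 to 0.926). The highest scores of these lists were those of Oxtriphylline (0.806), Probenecid (1.1), Ursodiol (1.3) and Aprepitant (1.24), in the same order. Neuron markers were lowest with Oxaprozin (-0.751) and highest with CE-326597 (0.421; vehicles, -0.32 to 0.271), and excitatory neuron markers lowest with Oxaprozin (-1.12) and highest with Luteolin (0.364; vehicles, -0.453 to 0.326). Inhibitory neuron markers were lowest with Fenofibrate (-0.625) and highest with Propranolol·HCl (0.353; vehicles, -0.285 to 0.342), and astrocyte markers lowest with Luteolin (-0.595) and highest with Ursodiol (0.634; vehicles, -0.361 to 0.398). The extremes of 218 drugs would mostly lie outside 9 vehicles without any drug effect, so these ranges are no test. Of the 3 highest and 3 lowest scores of each list, 120 (65%) lay outside the vehicle range once centred on their run code, none of them for hypoxia response, 1 for AhR targets and 2 each for cholesterol biosynthesis and for fibroblast, inhibitory neuron and mural cell markers. Clonazepam, for example, then scored -0.609 for activity-regulated genes, within the centred vehicles (-1.10 to 1.58).

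**Figure D4:**
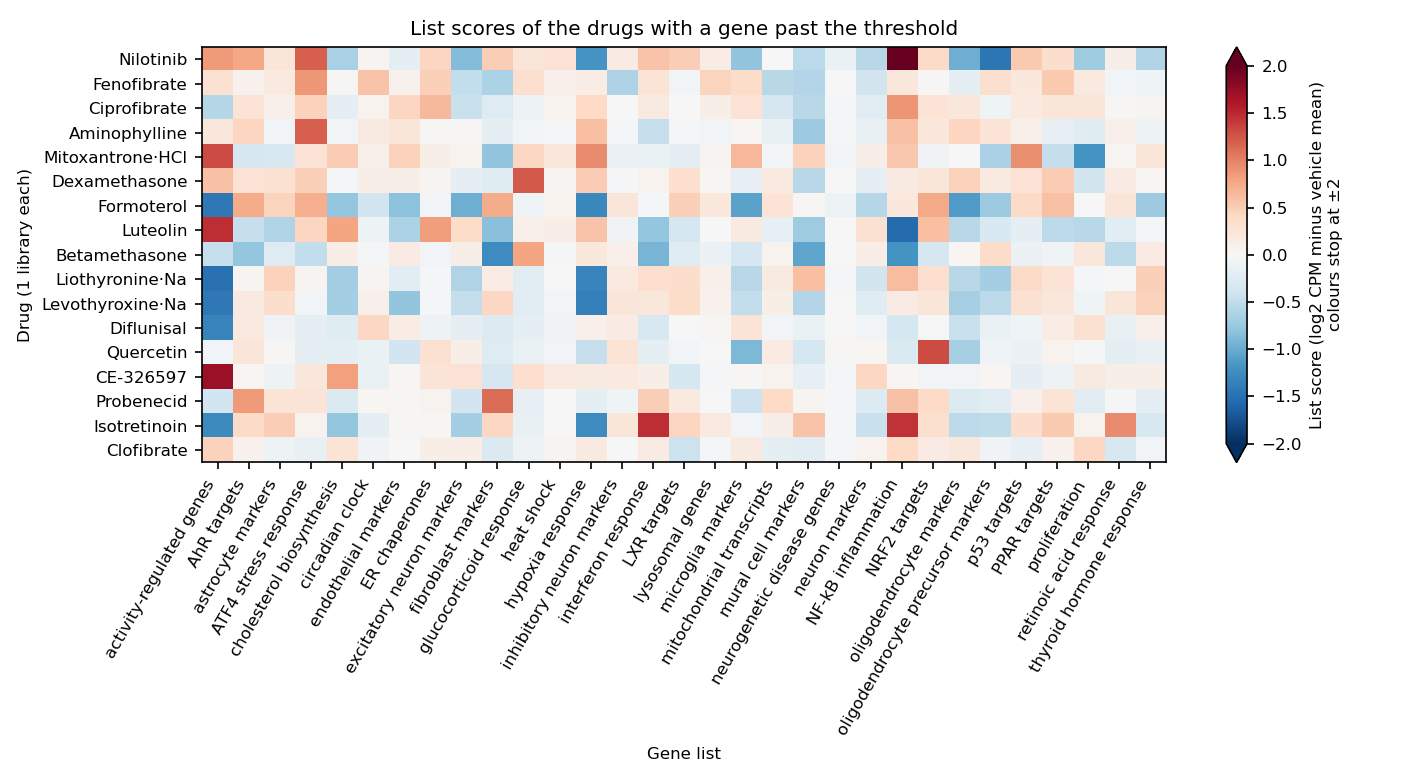
List scores of the drugs with a gene past the threshold. Nilotinib had the highest NF-kB inflammation score, 2.18.

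To ask which neurogenetic disease genes responded, 69 genes were followed in all 218 drugs. Of 15042 gene and drug pairs 19 passed, 6 as rises and 13 as falls, in 17 genes and in 2 drugs, Fenofibrate and Nilotinib (30 pairs in 22 genes and 7 drugs adjusted over the list alone; 0 pairs in the vehicles). The share of disease genes that passed was 14% with Fenofibrate and 13% with Nilotinib, close to the 11% and 12% of all genes tested. Atxn7, the gene of spinocerebellar ataxia type 7 (ENSMUSG00000021738.4, chromosome 14, 13961440 to 14107302), rose by 1.248 ± 0.113 with Fenofibrate (edgeR adjusted p = 0.000116) and 0.89 ± 0.117 with Nilotinib. Dnm1, a synaptic dynamin, fell with Nilotinib (-0.85 ± 0.181), and was taken alphabetically among 15 genes that passed in 1 drug. Disease gene scores were highest with CP-448187 (0.0503) and lowest with Nilotinib (-0.129; vehicles, -0.0161 to 0.0132). DESeq2 gave 89 pairs and limma with a run-code term 83.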

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

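The tests between drugs beyond the 9 fixed pairs, the run-code tests and the neuron, depth and Hsd11b1 tests below were chosen only after the result was seen.

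Aminophylline had a higher ATF4 stress response score than its relatives, a comparison of single libraries without a test. The score was 1.2, against 0.00892 for Theophylline and -0.569 for Oxtriphylline, the choline salt of theophylline (vehicle SD 0.269). Flagged as differences between groups, 2 genes separated Aminophylline from Theophylline and 3 separated it from Oxtriphylline, namely Cebpg, a partner of ATF4 (1.58 ± 0.183), Sltm (0.94 ± 0.104) and Insr (0.79 ± 0.0983), with none of 17 ATF4 stress response genes past the threshold in edgeR in either comparison. Centred on run code the scores were 0.941, 0.187 and -0.206, so most of the low value of Oxtriphylline went with its run code. A shared sequencing run could raise the score of Aminophylline, but it lay 0.709 above the highest of the 31 other libraries of its run code. A shift shared by that run code thus cannot be the whole of it. Aminophylline was chosen for its high score, and 1 library cannot separate the drug from an effect of that library alone. An unusual depth is excluded, since its 41.42 M counts fall within the vehicles (31.4 to 43.8). An effect of the culture itself or of an unknown dose was not tested.

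Glucocorticoid response genes set Cortisone Acetate apart from Dexamethasone and Betamethasone. The other two differed from it in 3 genes in edgeR, Tsc22d3 (1.969 ± 0.166, adjusted p 0.0012), Fkbp5 (2.135 ± 0.265, 0.029) and Map3k6 (4.03 ± 0.513, 0.029). Cortisone needs the enzyme encoded by Hsd11b1 to become active, and little of it could account for the difference, but a vehicle mean of 2.72 CPM (SD 1.29, highest 4.78) leaves this undecided. Centred on run code, the scores were 0.0837 for Cortisone Acetate, 1.27 for Dexamethasone and 0.881 for Betamethasone, against -0.174 to 0.314 in the vehicles. A shift shared by whole run codes thus cannot be all of the difference in score. The 3 libraries came from different run codes, and that of Cortisone Acetate held no vehicle. Run code was not modelled in the comparison of genes, so drug and run code cannot be told apart there. An unknown dose, or an effect of the Cortisone Acetate library alone, was not tested.

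Activity-regulated genes were below the vehicle range in all 5 benzodiazepine libraries, but once centred on run code Clonazepam (-0.609) and Oxazepam (-0.84) lay within it (-1.10 to 1.58). Sequencing run could account for part of this, but the mean centred score was still -1.16 (95% interval -1.70 to -0.616). A shift shared by whole run codes thus cannot be the whole of it. The interval treats the 5 libraries as independent, though they came from 4 run codes. Centring cannot remove a structure of the samples that crosses run codes. Fewer neurons could lower the list too, but the neuron marker median was -0.11 against -1.80, a difference of 1.69 (SE 0.277). The neuron markers thus did not fall by as much as the list. The SE treats the genes of a list as independent, and excitatory neuron markers had a median of -0.229. The activity-regulated score spanned -1.21 to 1.2 among the vehicles alone, so a smaller change in neurons cannot be excluded as a part of it. The number of genes is not secure, since 3 of 60 splits, the real one included, gave 569 or more and the highest other gave 6218. The splits counted genes and did not test the list. For glucocorticoids only 1 split, the real one, gave as many genes (highest other 1), but 2 genes against 1 cannot exclude chance. For the 5 classes split this way with a real count of 0 all 60 splits gave as many, a number fixed by the 0 that tests nothing.

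Other differences between groups were 3 genes between Luteolin and Apigenin, 93 between Fenofibrate and Ciprofibrate, and 170 between Fenofibrate and Clofibrate. The 2 libraries of each of these comparisons came from different run codes, which were not modelled, so drug and run code cannot be told apart in these counts. The same holds for the genes that separate Aminophylline from its relatives. Fenofibrate exceeded Ciprofibrate in Mx2 (3.96) and Snai2 (4.62), was below it in Sdf2l1 (-1.31), and exceeded Clofibrate in Mx2 (4.484 ± 0.41), Ddit3 (2.66) and Gdf15 (3.97), genes chosen after their values were seen.

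Libraries far from their group were vehicle library 4 for the circadian clock score (-0.193; others, -0.0438 to 0.073), Paroxetine·HCl for the percent of counts on Yam1 (5.94; other SSRIs, 2.76 to 3.53) and Triazolam for the same percent (2.55; other benzodiazepines, 5.1 to 5.8). The Dixon test used flags about 1 in 20 groups by chance, and 3 of 60 groups and measures were unusual where 3 are expected.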

How the results depend on the processing

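The tests without each vehicle library were chosen only after the result was seen; all other alternatives were fixed beforehand. No paired analysis was possible because the labels match no drug library to a vehicle library. RLE factors kept the counts of the 17 drugs, of the classes and of the pairs within 1.5 times, and gave 20 drugs with a call. Centring on run code kept the sign of the own-list score in 8 of 9 classes, with thyroid hormones at 0.785 in place of 0.471, tricyclic antidepressants at -0.163 in place of -0.363 and statins at -0.0233 in place of 0.0321, and 120 screen scores (65%) stayed outside the vehicle range. No named gene with a call changed direction, and Sgk1 (0.213), Klf9 (0.626), Sqle (0.193) and Hmgcs1 (0.24), without a call, changed sign with a run-code term; 2 lost their call with RLE factors, 24 without a filter, 6 in DESeq2 and 18 with a run-code term. Where counts moved, the cause was not tested. The run-code model also changed the reference from the vehicles to all other libraries, so its differences are not those of run code alone. Counts written with an exponent are rounded to 2 digits. With a lone library 65.7% of simulated changes of 1 log2 unit were recovered, and what depth limits was not tested.

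DESeq2, then limma with a run-code term, gave for Nilotinib 3265 and 3202, Fenofibrate 2496 and 4209, Ciprofibrate 564 and 544, Aminophylline 294 and 573, Mitoxantrone·HCl 364 and 234, Dexamethasone 1.3e+02 and 1.2e+02, Formoterol 851 and 1.5e+02, Luteolin 344 and 1384, Betamethasone 74 and 75, Liothyronine·Na 1.5e+02 and 1.2e+02, Levothyroxine·Na 94 and 1.2e+02, Diflunisal 334 and 43, Quercetin 32 and 44, CE-326597 87 and 600, Isotretinoin 13 and 5, and Clofibrate 31 and 3; DESeq2 gave Probenecid 14. No filter gave Ciprofibrate 71, Luteolin 25 and Diflunisal 8. Drugs above every vehicle numbered 32 and 28, and disease gene pairs 89 and 83.

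For classes the same alternatives gave glucocorticoids 45 and 1.7e+02, thyroid hormones 960 and 372, tricyclic antidepressants 510 and 3, flavonoids 1 and 374, fibrates 74 and 2045, and benzodiazepines 1291 and 1882 (345 without a filter). DESeq2 gave dihydropyridines 29. For pairs DESeq2 gave Dexamethasone and Betamethasone 1, Citalopram·HBr and Escitalopram 1, Luteolin and Apigenin 21, Quercetin and Kaempferol 16, Temazepam and Oxazepam 18, and Aminophylline and Theophylline 1.1e+02 (0 without a filter). Of 279 camera tests 61 passed with the preset correlation, 0 with an estimated correlation and 1 by fry.

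Leaving out 1 library gave Nilotinib 1046 to 2188, Ciprofibrate 19 to 120, Aminophylline 38 to 95, Mitoxantrone·HCl 30 to 79, Formoterol 20 to 80, Luteolin 16 to 30, Liothyronine·Na 12 to 24, Levothyroxine·Na 13 to 22, Diflunisal 2 to 21, Quercetin 5 to 8, CE-326597 0 to 4, Probenecid 0 to 4, Isotretinoin 1 to 3 and Clofibrate 0 to 1. For classes it gave glucocorticoids 0 to 78, thyroid hormones 23 to 306, tricyclic antidepressants 0 to 3 and benzodiazepines 1.6e+02 to 811.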

Other observations

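The relations between list scores below are tests chosen only after the result was seen. Across all libraries (218 drugs and 9 vehicles), cholesterol biosynthesis genes and LXR targets ran opposite ways (Pearson r = -0.924, Spearman rho = -0.928). The r was -0.924 without the 2 farthest libraries, -0.957 to -0.768 within the 9 run codes and -0.974 in the vehicles alone. Cholesterol biosynthesis genes were also opposed to astrocyte markers (r = -0.905, rho = -0.905; -0.908 without the 2 farthest; -0.955 to -0.738 within run codes; vehicles -0.918). Excitatory neuron markers were opposed to astrocyte markers (r = -0.902, rho = -0.924; -0.901 without the 2 farthest; -0.962 to -0.657 within run codes; vehicles -0.932). Activity-regulated genes ran with cholesterol biosynthesis genes (r = 0.825, rho = 0.817; 0.819 without the 2 farthest; 0.613 to 0.979 within run codes; vehicles 0.905). The lists of each pair shared 0 genes. The 4 relations were chosen among all 465 pairs of lists. With scores centred on the run-code mean and libraries permuted within run code, r was -0.911, -0.87, -0.86 and 0.779 in the same order, each with a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted permutation p of 2.2e-05 over the 465 pairs. Such relations were common, since 75% of the pairs passed that test.

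With Dexamethasone and Betamethasone fitted together against vehicle, the fit that leaves out Cortisone Acetate, 70 genes rose and 8 fell in edgeR. Besides Plin4 (4.944 ± 0.371) and Map3k6 (4.59 ± 0.226), Fam107a, a stress-induced actin-binding protein (2.32), Mfsd2a, a lysolipid transporter (2.248), Ada, adenosine deaminase (2.07), Pdk4, which limits glucose oxidation (2.03), and Mertk, a phagocytic receptor (1.96), rose. Etv4, a growth factor-responsive transcription factor (-0.97), Micall2 (-0.94) and Rasa3, a GTPase-activating protein (-0.45), fell. Of 20 glucocorticoid response genes 9 rose (13 adjusted over the list alone, median 0.91).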
